A study of Mus musculus with 15 samples.

How the data were processed

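RNA of basophils, eosinophils and natural helper cells sorted from the lungs of naive and papain-treated mice was sequenced. Per the labels' protocols, basophils were sorted as FceR1+ CD49b+ c-kit-negative cells, natural helper cells as lineage-negative cells positive for Thy1.2, IL-7 receptor alpha and CD25, and eosinophils as SiglecF+ cells of low Gr1 and no autofluorescence, split by CD11c in papain mice. Libraries were made from 10 ng of RNA after poly(A) selection with NEBNext kits, per the labels' protocols. TopHat 1.4.0 and Cufflinks 1.3.0 with the mm9 genome are named in the submitters' processing notes. The deposited table gives 1 score per gene symbol and library. Its header names only the samples, so the unit was read from the values and the tool: whole-number FPKM (a fragment count scaled to transcript length and library size), deposited after Cufflinks and rounded by the authors. The annotation, any filter and the rounding step are not stated in the notes. Read depth cannot be recovered from FPKM, so precision is given only by the spread between replicates.

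All 15 columns were mapped to 8 groups from the labels. The table holds 21110 gene rows. Digit-grouping commas were removed from 1008 cells, 3 cells with values next to 0 were set to 0, 25 rows whose symbols had turned into dates were kept but never named, and 5521 rows were 0 in every library. Small RNA genes made up 493 rows. Symbols were used as the file gives them; 19085 of them are in the reference list of gene names. The reference at hand is of another build than mm9, so no coordinates are given.

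Genes with 1 FPKM or more in at least 2 libraries (14257 genes) were tested as log2(FPKM + 1) with no further scaling in limma 3.58.1 (R 4.3.3). A single linear model with a coefficient per group was fitted to all 15 libraries (7 residual degrees of freedom, prior degrees of freedom 1.87), followed by eBayes with trend, two-sided tests and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Comparisons were papain against naive for each cell type and CD11c gate, the 2 gates with each other, the 3'UTRKO library with papain natural helper cells, and differences of papain responses between cell types. A gene counted as higher in a naive cell type when it passed against both others with a log2 difference of 2 or more. The design, alternatives, gene lists and naming rule were set before the data were examined, except where the text says otherwise.

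The 17 pathway lists were type 2 and growth factor cytokines, chemokines, chemokine receptors, cytokine receptors, IL-4 and IL-13 response, interferon response, cell cycle, glycolysis, unfolded protein response, immediate early genes, transcription factors of type 2 lymphocytes, granule proteins and proteases, eicosanoid enzymes and receptors, antigen presentation and costimulation, adhesion molecules, inflammatory mediators and oxidative phosphorylation. The 15 marker lists covered basophils, eosinophils, natural helper cells, mast cells, T cells, B cells, NK cells, neutrophils, monocytes and macrophages, alveolar macrophages, dendritic cells, epithelium, endothelium, fibroblasts and red blood cells. Lists were tested with camera at a preset correlation of 0.01, adjusted over each kind of list within a comparison, beside camera with an estimated correlation and fry; lists with fewer than 5 genes tested (red blood cells, 4) were only described. All 10 eosinophil, 5 of 10 basophil and 9 of 12 natural helper cell markers also belong to another list, and none of the 7 fibroblast, 12 epithelial or 8 endothelial markers does. The text names, for each comparison, the up to 8 genes with the largest rise and fall among called genes with a mean of 10 FPKM or more and no overlap of libraries. It also names up to 3 members per pathway list with a mean of 5 FPKM or more, 8 fixed genes (Il4, Il5, Il13, Il9, Il4ra, Ccl5, Ccl11 and Ccl24) and members of marker lists. For naive cell types it names 8 genes, and for differing responses 5 in each direction. Gene models without a name, and microRNA and small nucleolar RNA genes, were passed over. Some genes that the rule selects are not reported here.

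The pipeline was tested on simulated data with 200 changed genes among 14257, drawn from the real group means and rounded as the file is. Each gene was given the same spread in all libraries. In the data, replicates differed by a median of 0.138 on the log2 scale in papain natural helper cells and 0.585 in papain basophils. The simulated rates may therefore not hold for groups with more or less spread. At log2 changes of 1, 2, 3 and 4, 10%, 68%, 94% and 96% of changed genes were called in the basophil comparison, 12%, 74%, 86% and 90% for natural helper cells, 14%, 72%, 88% and 98% for CD11c-negative eosinophils and 12%, 56%, 74% and 88% for the 3'UTRKO comparison. False calls were 50 of 184, 40 of 171, 17 of 153 and 65 of 180, above the 5% that the threshold allows; 41, 36, 16 and 57 of them lay below 5 FPKM, and without rounding there were 9, 11, 1 and 11. Each comparison is therefore also given as a count of calls with a group mean of 5 FPKM or more. A list raised by a log2 of 1 was called in each simulated comparison, and other lists were called 0, 1, 0 and 0 times.

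Genes with a near-identical copy were found by sharing at least 20% of 40-base words (taken every 10 bases) with another gene in the reference transcripts, for 14090 genes with a sequence (98.83% of those tested). Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, robust eBayes, a minimum log2 change of 1, the compared groups alone, the replicate number as a block within each cell type, and leaving out each library. After seeing the data 3 more were added (genes without a near-identical copy, genes other than small RNAs, and calls with a group mean of 5 FPKM or more). For the naive libraries that both eosinophil gates share, 50 simulations without an effect were run, and, after seeing the data, a fit with 1 naive library for each gate and a list test without each naive library. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.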

Results

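The transcriptomes of 3 kinds of immune cell sorted from mouse lung were measured by RNA sequencing in 15 libraries. Basophils, eosinophils and natural helper cells, the innate lymphocytes also called group 2 innate lymphoid cells, came from naive C57BL6/J mice and from mice given 50 ug of papain per mouse into the nose over 3 days. Papain is a plant protease that acts as an airway allergen. The libraries fall into 8 groups. Naive basophils, papain basophils, naive eosinophils, naive natural helper cells and papain natural helper cells have 2 libraries each. Eosinophils of papain mice were sorted by surface CD11c into a negative and a positive gate, with 2 libraries each. A single library holds papain natural helper cells labelled 3'UTRKO, and the labels do not name the gene whose 3' untranslated region was removed. The values are FPKM rounded to whole numbers, so the read depth behind each value is unknown and no counting interval can be given. The FPKM values of a library summed to between 374841 and 570208, and 9995 to 13049 of the 21110 genes were above 0. Small RNA genes, such as microRNAs and small nucleolar RNAs, held between 6.77% and 26.0% of a library's total. Log2 changes are on the scale of log2(FPKM + 1) and are given with their standard error, and a gene counts as changed when limma's Benjamini-Hochberg adjusted p is under 0.05. The labels do not say whether replicates are separate animals, so these p-values measure only the spread between these samples.

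**Figure D1:**
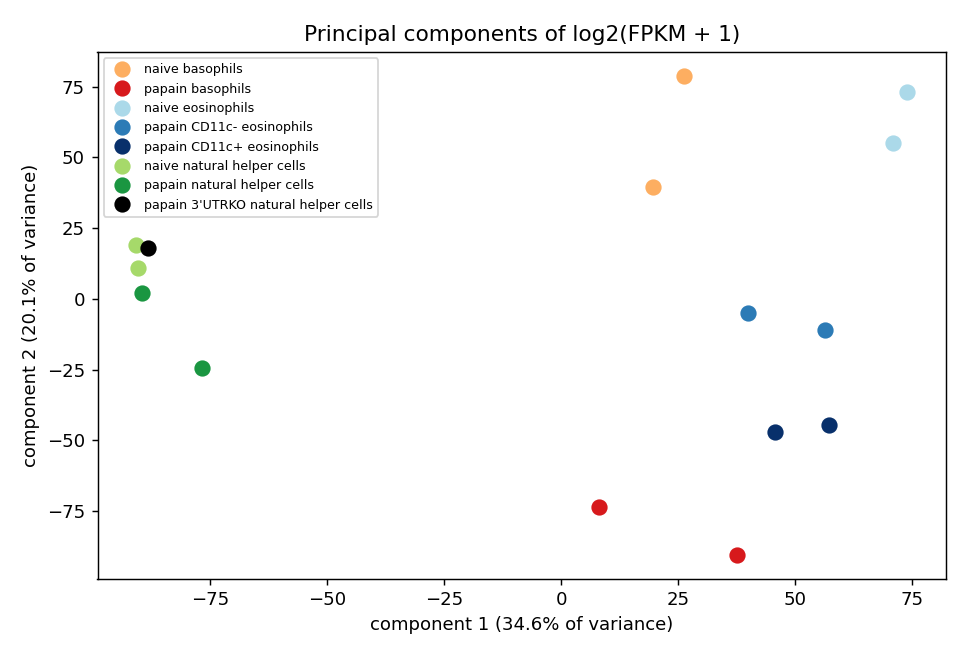
Principal components of log2(FPKM + 1), with component 1 (34.61% of the variance) on the x axis and component 2 (20.07%) on the y axis, 1 point per library, coloured by group. Libraries of natural helper cells lie to the left of all basophil and eosinophil libraries, and the papain libraries of basophils and eosinophils lie below the naive libraries of the same cell type.

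What sets the sorted cell types apart before treatment was the question of the naive comparisons. Naive basophils carried 146 genes above both other naive cell types by a log2 difference of 2 or more. Among them were the basophil protease Mcpt8 (824 and 252 FPKM, against at most 2 in naive eosinophils and 0 in naive natural helper cells) and the granzymes Gzmb (2582 and 2919) and Gzmc (1780 and 1670). The set also held the IgE receptor chain Fcer1a (141 and 194), the transcription factor Gata2 (664 and 845) and the steroid-synthesis enzyme Cyp11a1 (875 and 845). The smaller of the 2 log2 differences was 8.04 for Mcpt8, 9.25 for Gzmc and 8.75 for Cyp11a1. Naive eosinophils carried 306 such genes, with the granule major basic protein Prg2 (86 and 1519 FPKM), the granule ribonuclease Ear6 (91 and 333), the phospholipase Pla2g7, the inhibitory receptor Siglece (67 and 121) and the myeloid transcription factor Cebpe among those with the largest differences. Retnlg, a fixed marker of neutrophils, was also among them at 13759 and 7600 FPKM. Naive natural helper cells carried 414, led by Il5 (501 and 2283 FPKM), the eosinophil growth factor, which was listed at 0 in both other naive types. The set also held Ccl21a (103 and 102) and Stab2 (73 and 47), which are known from lymphatic and endothelial cells, and the chemokine receptor Cxcr6 (121 and 242). Further members were the chemokine Ccl1 (1100 and 1408), the chemokine receptor Ccr8 (291 and 309), the transcription factor Gata3 (168 and 273) and the costimulator Icos (100 and 201). Of the marker genes fixed for each type, 8 of 10 for basophils, 6 of 10 for eosinophils and 8 of 12 for natural helper cells were in these sets. Markers of other cells were present in naive libraries too: Scgb1a1, the secretory protein of club cells, had 6363 and 8531 FPKM in naive basophils, and fibroblast markers had a median of 18 and 26 FPKM in naive natural helper cells. B cell markers had medians of 19 and 32 FPKM in naive basophils, against 3 and 3 in naive eosinophils. Natural helper cells had 0 and 0. The naive basophil set also held 1 marker each of mast cells, B cells, epithelium, and monocytes and macrophages. Each gene had to pass limma against both other naive types. Without the naive basophil library 2 the natural helper cell set fell to 249 genes, the basophil set held 112 to 137 genes and the eosinophil set 225 to 325 when single libraries were left out.

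How lung basophils respond to papain was asked with 2 libraries a side. Basophil markers were lower after papain with and without an estimated correlation, and markers of fibroblasts, endothelium and epithelium were called higher by camera with the preset correlation and not with an estimated one. Il4, a type 2 cytokine that basophils secrete, fell from 353 and 319 FPKM to 42 and 122 (log2 change -2.21 ± 0.40, adjusted p = 0.00591). Il13, its close relative, fell from 169 and 226 to 20 and 71 (-2.34 ± 0.55, adjusted p = 0.0165). Both falls were smaller than the median fall of the fixed basophil markers (-2.77). They therefore cannot be told apart from a lower share of basophil RNA in the papain libraries. Cxcl1, a neutrophil-attracting chemokine, rose from 28 and 5 FPKM to 960 and 986 (6.21 ± 0.62, adjusted p = 0.000453). Ccl2, a monocyte-attracting chemokine, rose from 56 and 6 to 716 and 465 (4.85 ± 0.80, adjusted p = 0.00407). Of 14257 genes tested, 3152 rose and 553 fell, and the median of all genes was 0.50 higher on the log2 scale, so list medians are given relative to that value.

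Among the largest falls were the IL-18 receptor chain Il18rap (156 and 165 FPKM to 15 and 16, -3.29 ± 0.31), the lymphocyte surface protein Cd7 (232 and 244 to 24 and 23, -3.29 ± 0.56). Falls were also seen in the proteases Ctsg (35 and 11, then listed at 0) and Ctse (14 and 25 to 2 and 0), and Ufsp1 (14 and 7, then listed at 0). The basophil protease Prss34 fell from 700 and 48 to 7 and 20 (adjusted p = 0.0229, and 0.102 without papain library 1). The mast cell and basophil carboxypeptidase Cpa3 fell from 278 and 231 to 47 and 9 (adjusted p = 0.0166, and 0.057, 0.0796 or 0.0832 without naive library 1, naive library 2 or papain library 2). Il13 was at 0.103 without naive library 2 and 0.0557 without papain library 1. Among the largest rises were Retnla, a secreted protein induced by IL-4 and IL-13 (126 and 1 FPKM to 3714 and 2807), the matrix proteins Mgp (39 and 2 to 3141 and 1201) and Bgn (3 and 0 to 223 and 164). Others were the adhesion receptor Vcam1 (4 and 0 to 149 and 409), the protease inhibitor Serpina3n (0 in both naive libraries, then 168 and 40) and the goblet cell gene Clca3 (0 in both, then 91 and 173). The alarmin Il33, made mainly by epithelial and stromal cells, had 1 and 0 FPKM in naive and 20 and 32 in papain libraries (4.22 ± 0.47, adjusted p = 0.000689).

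All 10 fixed basophil markers were lower by value, 7 of them past the test (8 adjusted over the list alone), with a median of -3.27 relative to all genes (camera adjusted p = 4.1e-10, and adjusted p = 0.0182 with an estimated correlation). Fcer1a went from 141 and 194 FPKM to 23 and 18, and its partner chain Ms4a2 from 47 and 50 to 5 and 5. Mcpt8 went from 824 and 252 to 30 and 95, and Hdc, which makes histamine, from 2955 and 3199 to 375 and 1188. Fibroblast markers were higher by a median of 4.01 relative to all genes (6 of 7 called higher, 7 adjusted over the list alone; camera adjusted p = 0.00119, and adjusted p = 0.388 with an estimated correlation). Endothelial markers (6 of 8 called, 6 adjusted over the list alone) were 2.93 higher (camera adjusted p = 0.00448, and adjusted p = 0.47 with an estimated correlation). Epithelial markers (9 of 12, and 10 adjusted over the list alone) were 2.68 higher (camera adjusted p = 0.0182, and adjusted p = 0.506 with an estimated correlation). The surfactant gene Sftpc had 76 and 1 FPKM in naive and 498 and 760 in papain libraries. Fry, which tests whether a list's genes move 1 way and does not compare them with other genes, called fibroblast (adjusted p = 0.00164), endothelial (0.00462), epithelial (0.0185) and alveolar macrophage markers (0.0307) higher and basophil (0.000348) and B cell markers (0.0411) lower. Alveolar macrophage markers had 3 of 8 called higher (camera adjusted p = 0.0875), monocyte and macrophage markers 2 of 12 (0.119) and neutrophil markers 2 of 9 (0.866). Alveolar macrophage markers had a median of 1.5 and 2 FPKM in naive and 141 and 9 in papain libraries. The macrophage lists were called higher after median-ratio scaling (0.0215 and 0.042) and quantile normalization (0.00544 and 0.0101). Lower lists were B cell markers (3 of 9 called, median -2.31; adjusted p = 0.344 with an estimated correlation), NK cell markers (1 of 8, -1.39; 0.378) and mast cell markers (0 of 6, -2.62; 0.47). The call of the mast cell list was lost under both other scalings (0.0641 and 0.128), and the c-kit-negative gate of the sort should leave out mast cells. B cell markers had medians of 19 and 32 FPKM in naive and 13 and 2 in papain libraries. Whether B cells in the naive sorts account for their fall was not tested. Eosinophil markers were called lower (camera adjusted p = 0.0383, and adjusted p = 0.493 with an estimated correlation) with 2 of 10 members called lower and a median of -0.50 relative to all genes. This call was lost under both other scalings (0.158 and 0.266).

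Of the 17 pathway lists, camera called 3 higher and 6 lower in basophils, and none with an estimated correlation. Fry called 4 higher, namely glycolysis (adjusted p = 0.00222), oxidative phosphorylation (0.016), unfolded protein response (0.0183) and chemokines (0.0183), and 0 lower. Oxidative phosphorylation genes were higher (15 of 20 called, 16 adjusted over the list alone; median 0.51 above all genes; camera adjusted p = 0.00048, and adjusted p = 0.631 with an estimated correlation), with Cox5a, a subunit of the last respiratory complex, rising from 59 and 35 FPKM to 218 and 140. Unfolded protein response genes (11 of 17 called, 11 adjusted over the list alone) were called higher too (camera adjusted p = 0.0258, and adjusted p = 0.631 with an estimated correlation). So were glycolysis genes (9 of 15 called higher and 2 lower, 12 and 3 adjusted over the list alone), at a camera adjusted p of 0.0388, and adjusted p = 0.631 with an estimated correlation. The endoplasmic reticulum protein Creld2 rose from 10 and 6 to 52 and 44, and the glycolytic enzymes Pgam1 and Eno1 rose from 25 and 15 to 104 and 81 and from 30 and 23 to 101 and 98. Cytokine receptors were lower (7 of 26 called lower and 4 higher, the same numbers adjusted over the list alone; camera adjusted p = 0.000211, and adjusted p = 0.2 with an estimated correlation). Csf2rb2, the mouse IL-3 receptor beta chain, fell from 667 and 616 to 111 and 130, whereas Il13ra1 rose from 2 and 1 to 14 and 19. Adhesion molecules (3 lower and 2 higher of 14; 4 and 2 adjusted over the list alone) and type 2 and growth factor cytokines (4 lower and 3 higher of 15; 4 and 4 adjusted over the list alone) had camera adjusted p = 0.0258 each. Chemokine receptors (2 lower of 14; 1 adjusted over the list alone) and immediate early genes (3 lower and 2 higher of 22; the same adjusted over the list alone) had the same value. Granule proteins and proteases (5 lower of 16; 5 adjusted over the list alone; median -0.50 relative to all genes) had 0.00584. All 5 were at adjusted p = 0.631 with an estimated correlation. Relative to all genes the medians were -0.76 for cytokines, -0.56 for chemokine receptors and -0.47 for immediate early genes. Without that subtraction they were -0.26, -0.06 and 0.03, with means of 0.09, 0.02 and 0.06. The integrin Itgb7 fell from 96 and 94 to 31 and 15, and the chemokine receptor Cxcr4 from 769 and 470 to 179 and 106. Il6, named after its values were seen, fell from 2713 and 3535 to 1066 and 828, while Il5 (listed at 0, then 12 and 9) and the cytokine Lif (8 and 9 to 73 and 106) rose. Of 19 chemokines, 7 were called higher and 0 lower (8 and 0 adjusted over the list alone), with camera adjusted p = 0.258, and the list was called higher after quantile normalization (0.00621). The other lists were not called: interferon response (6 of 20 called higher, camera adjusted p = 0.0565, and called after quantile normalization at 0.0331), antigen presentation and costimulation (1 higher and 1 lower of 14, 0.166) and transcription factors of type 2 lymphocytes (3 and 2 of 14, 0.258). The same held for eicosanoid enzymes and receptors (4 and 2 of 19, 0.315), IL-4 and IL-13 response (6 and 3 of 19, 0.835), inflammatory mediators (7 and 2 of 18, 0.989) and cell cycle (3 and 0 of 29, 0.989). Marker lists of natural helper cells (0.115), T cells (0.119) and dendritic cells (0.866) were not called either, and red blood cell markers had a median of 0.49 before subtraction of the 0.50 of all genes. These pathway changes came with the marker shifts given above, in which fibroblast markers went from a median of 1 and 1 FPKM to 147 and 20.

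Of the 3705 calls, 2728 had a group mean of 5 FPKM or more, and leaving out single libraries gave 1228 (without naive library 2) to 3513 calls, and the compared groups alone gave 467. Among the calls, 85.07% were higher, against 65.5% after median-ratio scaling and 45.4% after quantile normalization, and only the oxidative phosphorylation and cytokine receptor lists were called under all 3 scalings. The list count of 9 was 5 without papain library 2. The papain replicates were the least alike of all groups (Pearson correlation across genes 0.841, and 24.59% of genes at 10 FPKM or more differed over 2-fold).

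**Figure D2:**
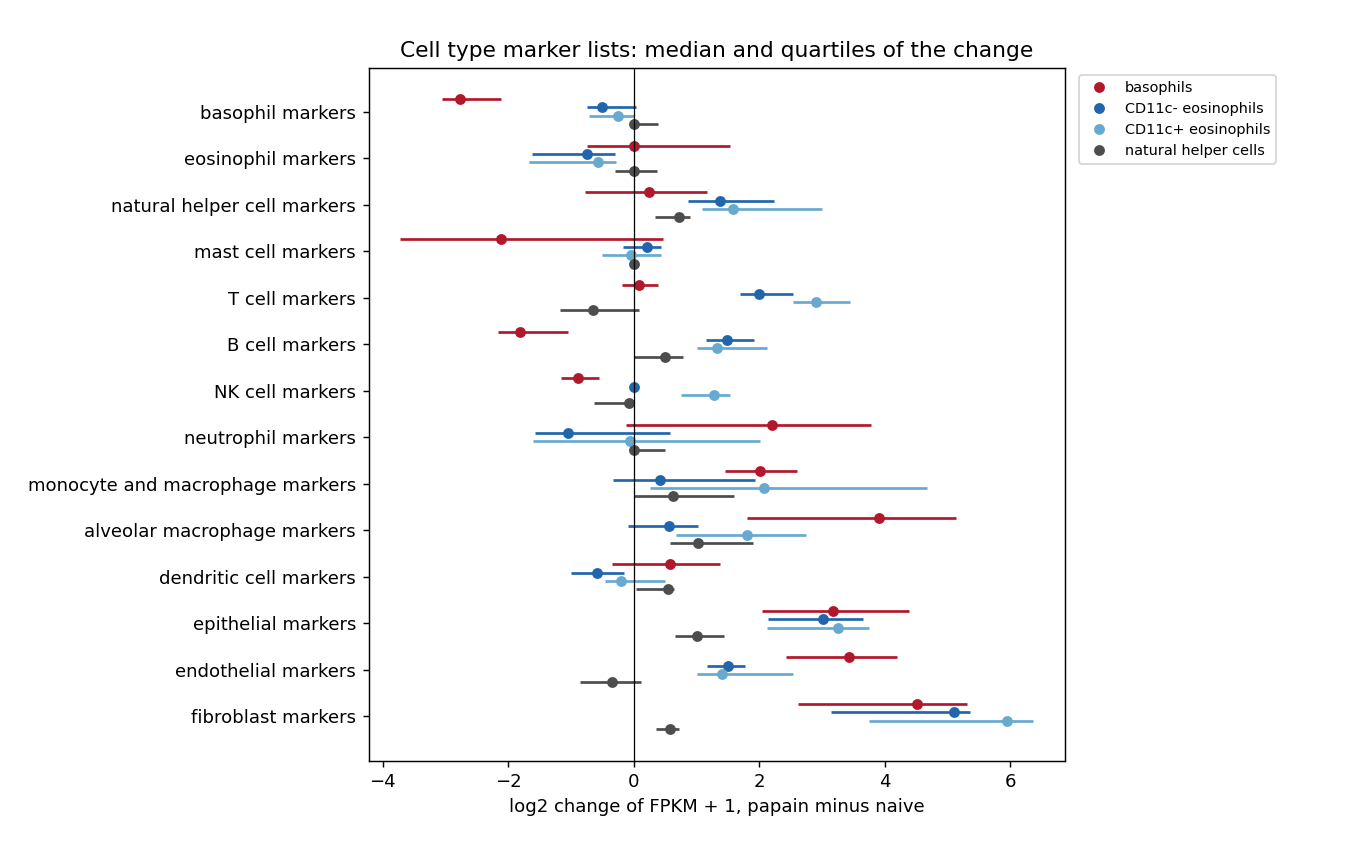
Median log2 change of FPKM + 1 (points) and quartiles (lines) of the genes of each fixed marker list, on the x axis, for papain against naive basophils, CD11c-negative eosinophils, CD11c-positive eosinophils and natural helper cells, with lists on the y axis. Fibroblast markers had medians of 4.51 in basophils, 5.10 and 5.95 in the 2 eosinophil gates and 0.57 in natural helper cells, and basophil markers had -2.77 in basophils.

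How natural helper cells respond to papain was asked with 2 naive and 2 papain libraries. Their main cytokines were high in both conditions. Il5 had 501 and 2283 FPKM in naive and 2379 and 2350 in papain cells (1.14 ± 0.57, adjusted p = 0.518). Il13 had 93 and 218, then 407 and 377 (1.45 ± 0.55, adjusted p = 0.347), and Il4 had 19 and 25, then 20 and 24 (0.01 ± 0.40, adjusted p = 1). Il2, the T cell growth factor, fell from 91 and 99 to 23 and 15 (-2.29 ± 0.30, adjusted p = 0.0105). Il1r2, the decoy receptor for interleukin-1, rose from 6 and 2 to 66 and 68 (3.89 ± 0.52, adjusted p = 0.0111). Across all genes 77 rose and 35 fell.

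The other large rises were the phosphatase Dusp4 (5 and 6 to 68 and 75 FPKM), Endod1 (5 and 6 to 48 and 56), Ttc39c (6 and 15 to 85 and 84) and the matrix protein tenascin C, Tnc (1 and 1 to 8 and 16). They also included the transporter Slc15a3 (10 and 10 to 56 and 58), Serinc5 (10 and 11 to 55 and 61) and the galectin Lgals3, also abundant in macrophages (28 and 13 to 71 and 115, the latter in the papain library with the most macrophage markers). The recombinase gene Rag1 (15 and 10) and Syt13 (19 and 18) were listed at 0 in both papain libraries, at adjusted p = 2.16e-05 and 1.01e-06. Dntt, the terminal transferase of developing lymphocytes, went from 12 and 23 to 0 in both, and Ly6d, a surface protein of early lymphoid cells, from 16 and 19 to 0 and 1. Of these, Serinc5 kept its call without each of the 4 libraries in turn, and Rag1 and Syt13 in the 2 such fits in which they were tested. Adjusted p reached 0.0921 for Il1r2 (without papain library 2; also lost without papain library 1 or naive library 2) and 0.0921 for Il2 (without papain library 2; also lost without either naive library). It reached 0.28 for Dusp4 and 0.273 for Endod1 (lost without any 1 of the 4), 0.16 for Ttc39c, 0.152 for Tnc, 0.0773 for Slc15a3 and 0.284 for Lgals3, all highest without papain library 2. It was up to 0.0709 for Dntt (without papain library 2) and 0.129 for Ly6d (without papain library 1). Irf4, a transcription factor of activated lymphocytes, had 5 and 7 FPKM in naive and 65 and 73 in papain cells (3.33 ± 0.68, adjusted p = 0.0784). Tnfsf4, the ligand of OX40, had 6 and 8, then 81 and 76 (3.32 ± 0.62, adjusted p = 0.0539).

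Camera called 7 pathway lists higher and 1 lower, and none with an estimated correlation, and fry called glycolysis genes (adjusted p = 0.00116) and cytokine receptors (0.0282) higher. Glycolysis genes were higher (14 of 15 by value, 4 called and 11 adjusted over the list alone; median 0.77; camera adjusted p = 3.83e-12, and adjusted p = 0.0921 with an estimated correlation). Eno1 rose from 38 and 43 FPKM to 100 and 107 (1.33 ± 0.16, adjusted p = 0.00487, and 0.057 without papain library 2). Pgam1 rose from 15 and 17 to 62 and 61 (adjusted p = 0.0256; lost without any 1 of the 4 libraries, up to 0.191 without papain library 2). Cell cycle genes were higher in 28 of 29 by value, with 0 called and 0 adjusted over the list alone (median 1.18; camera adjusted p = 9.69e-06, and adjusted p = 0.635 with an estimated correlation). The proliferation marker Mki67 had 4 and 5, then 23 and 17 FPKM, and the topoisomerase Top2a 4 and 8, then 34 and 22. Unfolded protein response genes had 0 members called and 7 of 17 adjusted over the list alone (camera adjusted p = 0.000646, and adjusted p = 0.635 with an estimated correlation). Immediate early genes were lower in 19 of 22 by value, with 0 called and 2 adjusted over the list alone (median -0.56; camera adjusted p = 7.09e-08, and adjusted p = 0.335 with an estimated correlation). Fosb had 634 and 354, then 156 and 154 FPKM, and Egr1 103 and 59, then 23 and 29. Cytokine receptors were called higher (1 of 26 called, 6 adjusted over the list alone; camera adjusted p = 0.0123, and adjusted p = 0.335 with an estimated correlation). So were antigen presentation and costimulation genes (0 of 14 called, 2 adjusted over the list alone; 0.0274, and adjusted p = 0.635 with an estimated correlation). Adhesion molecules (0 of 14 called, 2 adjusted over the list alone; 0.0455) and oxidative phosphorylation genes (0 of 20 called, 4 adjusted over the list alone; 0.0142) followed, at adjusted p = 0.635 and 0.734 with an estimated correlation. Adhesion molecules and oxidative phosphorylation were not called under either other scaling, at camera adjusted p of 0.0508 and 0.166 after median-ratio scaling and 0.0546 and 0.19 after quantile normalization. Small RNA genes held 26.0% and 22.4% of the total in the naive libraries, 14.0% and 11.7% in the papain libraries and 17.9% in the 3'UTRKO library. Whether this share bears on the lists was not tested. Papain library 2 stood apart in macrophage markers. Its alveolar macrophage markers had a median of 24 FPKM (sum 974), against 2.5 (sum 173) in papain library 1 and 3 and 0.5 in the naive libraries, and its monocyte and macrophage markers had a sum of 504, against 169 in papain library 1 and 235 and 158 in the naive libraries. No marker list of another cell type was called, the nearest being T cell markers (median -0.65, camera adjusted p = 0.131), and epithelial markers (median 1.00, adjusted p = 0.2) were called after quantile normalization (0.0357).

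Of the 112 calls, 59 had a group mean of 5 FPKM or more, and leaving out single libraries gave 52 (without papain library 1) to 126 calls. At an unadjusted p under 0.05 there were 1551 genes; 68.75% of the calls were higher, against 38.5% after median-ratio scaling (52 calls) and 53.6% after quantile normalization (56 calls). The balance turned round to 55 higher and 71 lower without naive library 2 and to 20 and 35 without papain library 2, the compared groups alone gave 521 calls, and the list count of 8 fell to 4 (2 higher, 2 lower) without naive library 1.

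How eosinophils respond to papain was asked for each CD11c gate against eosinophils of naive mice. In both gates single chemokine and matrix genes rose, though in the CD11c-negative gate the chemokine list was not called (3 of 19 called, 6 adjusted over the list alone; camera adjusted p = 0.24) except after quantile normalization, where it was called higher (0.00307). Ccl7, a monocyte-attracting chemokine, rose from 1 and 2 FPKM in naive eosinophils to 126 and 129 in the CD11c-negative gate (5.71 ± 0.43, adjusted p = 0.00106) and to 390 and 392 in the CD11c-positive gate (7.32 ± 0.43, adjusted p = 0.000114). Dcn, the matrix proteoglycan decorin, rose from 1 and 1 to 137 and 99 (5.88 ± 0.55, adjusted p = 0.00294) and to 200 and 200 (6.65 ± 0.55, adjusted p = 0.000506). Il4 did not pass the test in either gate: it had 126 and 110 FPKM in naive, 95 and 114 in CD11c-negative (adjusted p = 0.966) and 179 and 200 in CD11c-positive eosinophils (adjusted p = 0.312). In the CD11c-negative gate 267 genes rose and 53 fell, and in the CD11c-positive gate 1416 rose and 314 fell. With the compared groups alone the order of the gates turned round, with 1024 calls in the CD11c-negative and 735 in the CD11c-positive gate. The median of all genes was 0.21 higher in the former and 0.34 higher in the latter.

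In the CD11c-negative gate the matrix gene Sparc rose from 1 and 2 FPKM to 141 and 80, and Lif rose from 2 and 2 to 35 and 23. Ccl2 rose from 3 and 8 to 291 and 224 (adjusted p = 0.0113, up to 0.117 without naive library 1). The collagen Col3a1 rose from 0 in both to 74 and 29 (adjusted p = 0.0099, up to 0.0926 without naive library 1) and Il5 from 0 in both to 25 and 15 (adjusted p = 0.0069, up to 0.071 without naive library 1). Falls were smaller. Ltb, the lymphotoxin beta subunit, fell from 620 and 393 to 133 and 105 (-2.05 ± 0.26, adjusted p = 0.00631, and 0.0548 without naive library 1). The glucose transporter family member Slc2a6 fell from 122 and 88 to 27 and 17 (adjusted p = 0.00559, and 0.0657 without naive library 1). The receptor Kit fell from 27 and 19 to 7 and 3 (adjusted p = 0.0122, and 0.123 without naive library 1) and Naaladl1 from 17 and 15 to 3 and 3. The transcription factor Ets1 rose from 10 and 9 to 35 and 67. Among the 17 pathway lists adhesion molecules were called, lower (1 of 14 called, 2 adjusted over the list alone; median -0.74 relative to all genes; camera adjusted p = 5.14e-05, and adjusted p = 0.826 with an estimated correlation). After quantile normalization 7 lists were called, with chemokines (0.00307), glycolysis genes (0.00307), type 2 and growth factor cytokines (0.00707), unfolded protein response genes (0.00947), transcription factors of type 2 lymphocytes (0.0102) and oxidative phosphorylation genes (0.0407) higher. Fry called 0 of the 17 lists (lowest adjusted p = 0.118). The list count by camera was 5 without naive library 1 (1 higher, 4 lower) or CD11c-negative library 1 (2 higher, 3 lower), and 2 without CD11c-negative library 2. Its called member Itgb7 went from 117 and 94 to 42 and 39 (adjusted p = 0.0437, and up to 0.323 without naive library 1). Eosinophil markers were lower by a median of -0.95 relative to all genes, with 0 of 10 called and 0 adjusted over the list alone (camera adjusted p = 0.00251, adjusted p = 0.307 with an estimated correlation, and 0.0861 after quantile normalization). Their median was 51 and 168 FPKM in the naive and 64.5 and 52 in these papain libraries, so this fall rests largely on naive library 2, and without it camera adjusted p was 0.176.

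In the CD11c-positive gate the same 8-gene rule gave, beside Ccl7 and Dcn, rises of Mgp (6 and 20 FPKM to 1813 and 1769) and Ccl2 (3 and 8 to 654 and 766). It also gave rises of elastin, Eln (0 in both to 118 and 100), Col3a1 (0 in both to 105 and 89), Igfbp7 (0 and 4 to 209 and 214) and dermatopontin, Dpt (0 and 1 to 114 and 140). Itga4, the integrin alpha 4 chain that binds Vcam1, fell from 105 and 119 to 8 and 9 (-3.57 ± 0.51, adjusted p = 0.00405). Rcsd1 fell from 187 and 149 to 19 and 22, Tbc1d2b from 60 and 44 to 7 and 4, and the sulfotransferase Chst13 from 37 and 36 to 7 and 3. Naaladl1 fell from 17 and 15 to 1 and 1, and the granule protein Prg3 from 10 and 63 to 3 and 0 (adjusted p = 0.0224, and 0.0893 or 0.131 without naive library 2 or papain library 2). Il6 rose from 91 and 75 to 441 and 440 (2.40 ± 0.31, adjusted p = 0.00233). Lif (2 and 2 to 63 and 56), Il5 (0 in both to 16 and 14) and Il33 (0 in both to 13 and 7) rose too. Eotaxin-1, Ccl11, was listed at 0 in naive eosinophils and at 77 and 79 here (adjusted p = 0.0114, up to 0.0764 without naive library 1). The splicing target of the unfolded protein response, Xbp1, rose from 18 and 26 to 80 and 75, and the chaperone Dnajb9 from 10 and 12 to 42 and 43.

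Camera called 5 pathway lists higher and 2 lower in the CD11c-positive gate, all at adjusted p = 0.833 with an estimated correlation. Fry called 8 higher and 0 lower, among them cytokines (adjusted p = 0.00811), chemokines (0.0178), unfolded protein response genes (0.0189) and oxidative phosphorylation genes (0.0498). The list count by camera of 7 fell to 1 without CD11c-positive library 1 (1 higher) or library 2 (1 lower), and to 4 without naive library 2. Higher were unfolded protein response genes (7 of 17 called, 9 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.013) and oxidative phosphorylation genes (1 of 20, 4 adjusted over the list alone, 0.0145, and 0.175 after median-ratio scaling). Also higher, at 0.0472 each, were chemokines (6 of 19, 6 adjusted over the list alone), type 2 and growth factor cytokines (3 of 15, 4 adjusted over the list alone) and cell cycle genes (1 of 29, 0 adjusted over the list alone). Adhesion molecules (2 of 14 called lower, 2 adjusted over the list alone, 0.00196) and granule proteins (1 of 16, 1 adjusted over the list alone, 0.0472, and 0.189 and 0.265 after median-ratio scaling and quantile normalization) were lower. Glycolysis genes and inflammatory mediators, not called (0.107 and 0.142), were called higher after quantile normalization (0.0274 and 0.0132). With these lists moved markers of other cells. Fibroblast markers were higher by 4.89 in the CD11c-negative and 5.61 in the CD11c-positive gate relative to all genes (5 and 6 of 7 called, 6 in each adjusted over the list alone; camera adjusted p = 4.2e-08 and 4e-05; adjusted p = 0.29 and 0.439 with an estimated correlation). Epithelial markers were higher by 2.80 and 2.91 (2 and 5 of 12 called, 8 and 10 adjusted over the list alone; 7.61e-07 and 0.00148; adjusted p = 0.29 and 0.456 with an estimated correlation). T cell markers were higher by 1.79 and 2.56 (0 and 2 of 10 called; adjusted p = 0.395 and 0.648 with an estimated correlation) and natural helper cell markers by 1.16 and 1.24 (1 and 3 of 12; adjusted p = 0.29 and 0.439). In both gates fry called the fibroblast (adjusted p = 0.00353 and 0.00121), epithelial (0.0186 and 0.0201) and natural helper cell markers (0.0186 and 0.014) higher. Apoe, abundant in macrophages, had 24 and 20 FPKM in naive, 95 and 151 in CD11c-negative and 569 and 523 in CD11c-positive libraries. Eosinophil markers were called lower in the CD11c-positive gate, with 2 of 10 members called (camera adjusted p = 0.00413, and adjusted p = 0.439 with an estimated correlation). Their median was 71.5 and 75.5 FPKM there, above the 51 of naive library 1, and without naive library 2 camera adjusted p was 0.0789. In the CD11c-negative gate B cell markers (0 of 9 called; camera adjusted p = 0.00737) and endothelial markers (0 of 8; 0.00737) were called higher, and basophil markers (0 of 10; 0.0143) and dendritic cell markers (0 of 8; 0.00974) lower. With an estimated correlation adjusted p was 0.395, 0.395, 0.29 and 0.395, and the basophil call was lost after median-ratio scaling (0.0812). In the CD11c-positive gate basophil markers were also called lower (0 of 10; 0.0384, and adjusted p = 0.439 with an estimated correlation), a call lost under both other scalings (0.138 and 0.0933). Endothelial markers (0.0742) were called higher there after median-ratio scaling (0.0374) and quantile normalization (0.0191), and markers of monocytes and macrophages (0.202; median 1 and 2.5 FPKM in naive and 57 and 47 in CD11c-positive libraries) after quantile normalization (0.0481).

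Both gates were set against the same 2 naive libraries. The 2 sets of log2 changes correlated across genes at 0.751, against 0.504 in 50 simulations of unchanged groups against shared controls, with a covariance of 0.623 against 0.155, a difference of 0.469. At an unadjusted p under 0.05, 1640 genes passed in both with the same sign, against 168 in the simulations. These simulations drew genes independently, with the same spread in all libraries and without rounding to whole FPKM. Rounding raised false calls in the test of the pipeline, so the 168 may be too low. Higher in both after adjustment were 263 genes, against 26.5 for independent lists, and lower in both were 52, against 1.17. With 1 naive library for each gate, a test added after these values were seen, the gates shared no control. The correlation was then 0.571 or 0.553 and the covariance 0.537 or 0.51, depending on which library served which gate. Higher in both were 86 or 34 genes (1.98 or 1.52 for independent lists) and lower in both 17 or 9 (0.147 or 0.14). The CD11c-negative count of 320 fell to 44 without naive library 1 and was at most 161 (without CD11c-negative library 2) in every fit that left out 1 library of the 4; 231 of the calls had a group mean of 5 FPKM or more. The CD11c-positive count of 1730 went from 371 (without naive library 1) to 2070 (without CD11c-positive library 1), and 1310 of its calls had a group mean of 5 FPKM or more. Of the calls, 83.44% were higher in the CD11c-negative and 81.85% in the CD11c-positive gate, against 72.9% and 56.7% after median-ratio scaling and 73.5% and 51.2% after quantile normalization.

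**Figure D3:**
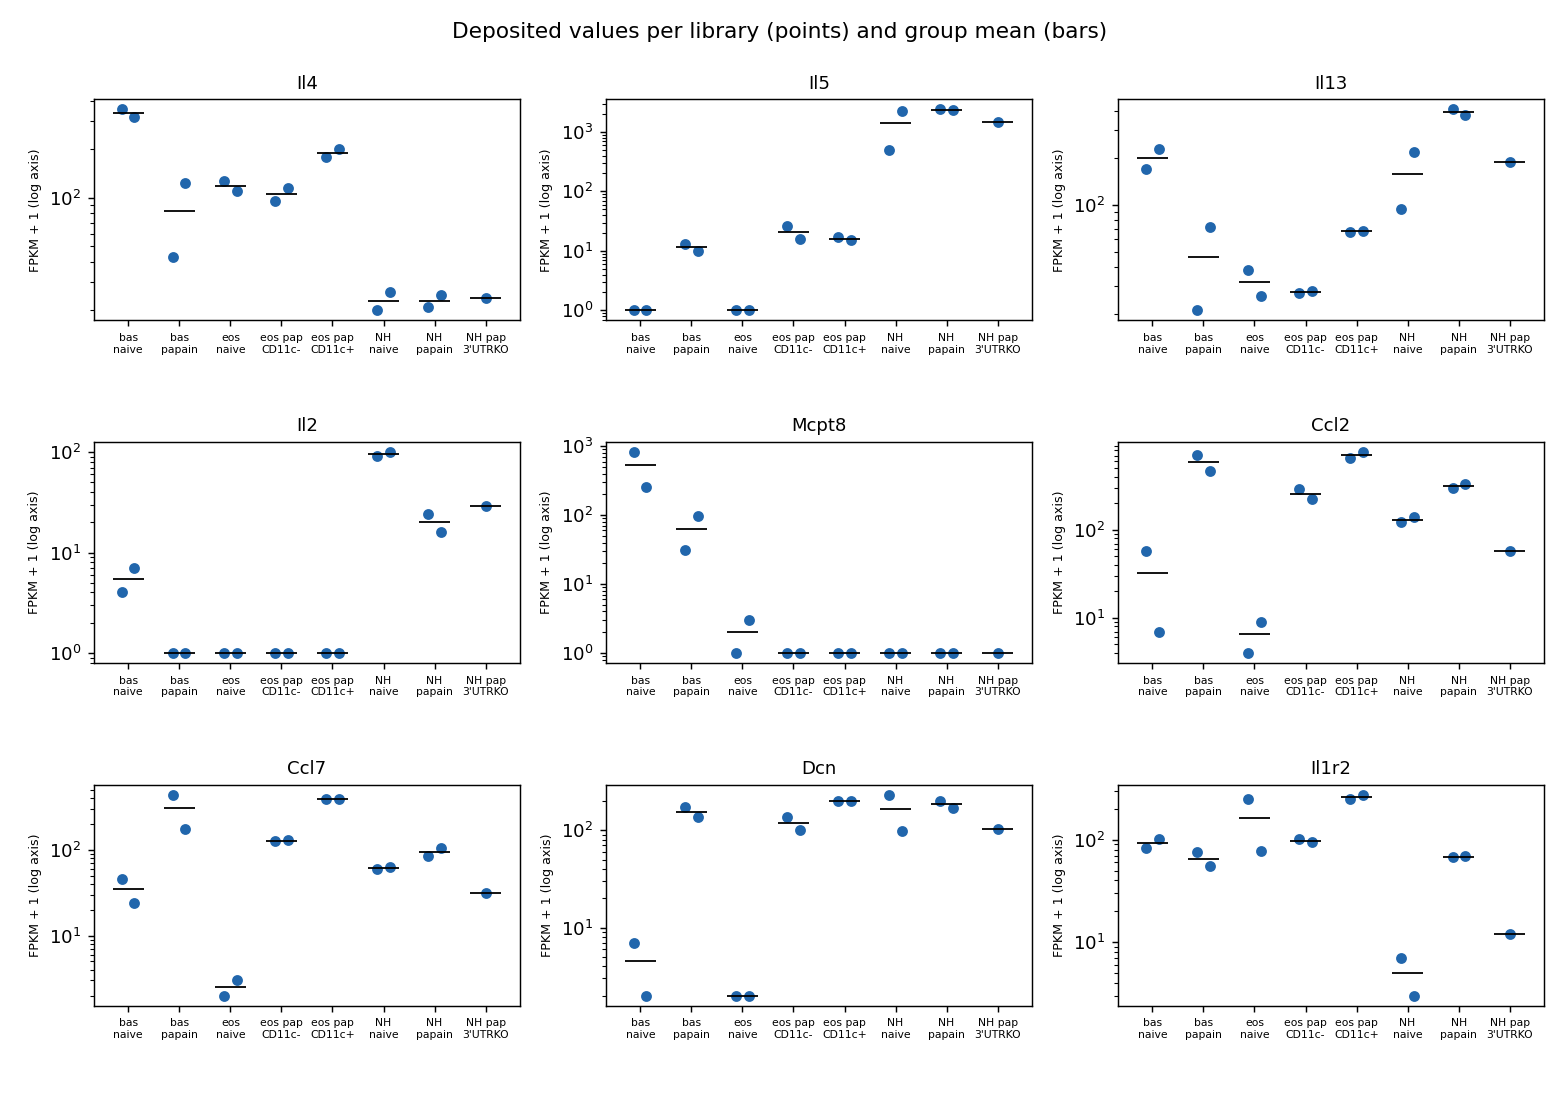
FPKM + 1 on a log axis (y) for 9 genes in each library (points) with the mean of each group (bars), by group (x; bas, basophils; eos, eosinophils; NH, natural helper cells; pap, papain). Il5 lies between 501 and 2379 FPKM in the natural helper cell libraries and at 25 or below in the others, and Mcpt8 is at 0 in all natural helper cell libraries.

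The 2 gates of papain eosinophils differed in few single genes by this test. Itgax, which encodes CD11c, had 109 and 185 FPKM in the CD11c-negative and 186 and 165 in the CD11c-positive gate. Limma called 8 genes, 4 higher and 4 lower in the CD11c-positive gate, and 1283 had an unadjusted p under 0.05. All 8 fell outside the rule for named genes and are named after their values were seen. Mir139 was listed at 0 in the CD11c-negative libraries and at 705 and 11202 in the CD11c-positive ones, and Slc13a3, Ccdc67, Trim6, Gnao1, Megf11, Pkd1l2 and Syt8 had at most 3 FPKM in all 4 libraries. By value, Ccl22 had 5 and 5 against 37 and 41 FPKM, Ccl24 1 and 2 against 11 and 20, Il13 26 and 27 against 66 and 67, and Itga4 37 and 26 against 8 and 9, with adjusted p of 0.601, 0.515, 0.551 and 0.465. Camera called 6 pathway lists higher in the CD11c-positive gate, and none with an estimated correlation, and fry called none (lowest adjusted p = 0.28). They were oxidative phosphorylation (19 of 20 higher by value, camera adjusted p = 0.000311), unfolded protein response (16 of 17, 0.00187) and inflammatory mediators (17 of 18, 0.00498). The others were interferon response (17 of 20, 0.0147), immediate early genes (20 of 22, 0.0147) and chemokines (16 of 19, 0.0351), at adjusted p between 0.74 and 0.766 with an estimated correlation. None of their members was called, and adjusted over the list alone 2 unfolded protein response genes were. Cell cycle genes (0.111) were called higher after median-ratio scaling (0.0356) and quantile normalization (0.0256), and IL-4 and IL-13 response genes (0.126) after median-ratio scaling (0.0465). Markers of monocytes and macrophages (9 of 12 higher, median 1.68) and NK cells (7 of 8, 1.37) lay at camera adjusted p = 0.0556 each and were called after median-ratio scaling (0.0113 each) and quantile normalization (0.0208 and 0.0123). Alveolar macrophage markers were not called between the gates (median 1.32, camera adjusted p = 0.303, and 0.113 and 0.132 after the other scalings). They had medians of 4 and 3.5 FPKM in naive, 8 and 6.5 in CD11c-negative and 17.5 and 18.5 in CD11c-positive libraries. The count of 8 went from 2 (without CD11c-negative library 1) to 498 (without CD11c-positive library 1) and was 157 (67 higher, 90 lower) with the compared groups alone. The list count of 6 fell to 1 without CD11c-positive library 1 and 3 without CD11c-negative library 2, and CD11c-positive library 2 had the fewest genes at a value of 1 of all libraries (1164).

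The difference of 3'UTRKO from other papain natural helper cells was asked with 1 library against 2. The lone library is assumed to vary like the other groups, and this comparison has no replicate check of its own. It is also the only library without Xist and with Y-linked transcripts, so sex and genotype cannot be separated in any value below. As the targeted gene is not named in the labels, the deletion could not be checked. Type 2 cytokines did not pass the test. Il4 had 20 and 24 FPKM in the papain libraries and 23 in the 3'UTRKO library (0.07 ± 0.49, adjusted p = 1), Il5 had 2379 and 2350 against 1443 (-0.71 ± 0.69, adjusted p = 0.919), and Il13 had 407 and 377 against 186 (-1.07 ± 0.67, adjusted p = 0.729). The calls were led by ribosomal protein genes. Rpl26 was at 901 and 969 FPKM against 0, Rps27 fell from 2704 and 2778 to 27 (-6.61 ± 0.30, adjusted p = 1.69e-05), Rpl34 from 1231 and 1222 to 28, and Rpl30 from 941 and 1010 to 42. Rpl17 rose from 652 and 677 to 2341 (1.82 ± 0.18, adjusted p = 0.00287).

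Of 83 ribosomal protein genes, 7 were called higher and 4 lower, which made up 13.6% of the 81 calls against 0.58% of all genes (Fisher's exact p = 1.14e-12; the family was tested after its values were seen). That test takes genes as independent and was not matched for expression, so its p-value does not measure a difference between samples. Rpl23a (665 and 725 to 2814; adjusted p = 0.0569 without papain library 1), Rpl11 (596 and 645 to 2292; up to 0.123 without papain library 1), Rpl31 (213 and 228 to 808; up to 0.0598 without papain library 1) and Rpl21 (123 and 137 to 621; up to 0.152 without papain library 1) rose as well. Near-identical gene copies, with which reads can be shared, were held by 35.4% of the 79 called genes with a known sequence and by 8% of uncalled genes, so these values are uncertain. Rpl34 (9.2% of its sequence words shared) and Rpl30 (12.2%) lay below the 20% set for such a copy, and within the family 81.8% of the called and 68.1% of the uncalled genes had one (Fisher's exact p = 0.491, a test added after the values were seen). Outside this family, Wdr89 fell from 64 and 71 to 1, the ribonuclease Rnaset2b from 76 and 83 to 3, and Xist, the RNA of the inactive X chromosome, went from 82 and 80 to 0. Rnaset2b shared 84.2% of its sequence words, above the 20% set for a copy, so its value is uncertain too. Wdr89 shared 14.3%. The Y-linked genes Ddx3y and Eif2s3y had 41 and 47 FPKM in this library and 0 in the other 14, where Xist was between 21 and 85.

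Camera called 4 pathway lists lower and 1 higher in the 3'UTRKO library, and none with an estimated correlation, and fry called none (lowest adjusted p = 0.0653). Cell cycle genes were lower in 27 of 29 by value (0 called, 4 adjusted over the list alone; median -1.64; camera adjusted p = 3.96e-08, and adjusted p = 0.658 with an estimated correlation), such as Mki67 (23 and 17 against 2). Glycolysis genes (14 of 15 lower by value, 0 called, 5 adjusted over the list alone) were lower (camera adjusted p = 1.83e-05, and adjusted p = 0.637 with an estimated correlation). Unfolded protein response genes were lower in 17 of 17 (0 called and 0 adjusted over the list alone; 7.73e-05, and adjusted p = 0.658 with an estimated correlation). Immediate early genes were higher in 18 of 22 (0 called and 0 adjusted over the list alone; 7.75e-05, and adjusted p = 0.658 with an estimated correlation), such as Fosb (156 and 154 against 479). Oxidative phosphorylation genes were lower too (17 of 20 by value, 0 called and 0 adjusted over the list alone; camera adjusted p = 0.000305, adjusted p = 0.817 with an estimated correlation, and 0.0519 after quantile normalization). The chemokine list (median -1.16) was not called at a camera adjusted p of 0.112, and was called lower after median-ratio scaling (0.0108) and quantile normalization (0.0192). The papain libraries enter this comparison and the naive comparison with opposite signs, so chance values in them push these lists in opposite directions. No marker list of another cell type was called; fibroblast markers had the largest change (median -1.15, camera adjusted p = 0.177). Alveolar macrophage markers (median -0.87, camera adjusted p = 0.784) had medians of 2.5 and 24 FPKM in papain libraries 1 and 2 (sums 173 and 974) and 2.5 in the 3'UTRKO library (sum 115), so 1 of the 2 control libraries stood apart in them. Without that library camera called 5 pathway lists, 1 higher and 4 lower. Of the 81 calls (30 higher, 51 lower), 52 had a group mean of 5 FPKM or more, and 25 were left without papain library 1 and 30 without papain library 2. Of the calls 37.04% were higher, against 48.1% after median-ratio scaling and 46% after quantile normalization. The balance turned round to 148 higher and 67 lower without a filter and to 71 and 48 with a pseudocount of 5, and the compared groups alone gave 2719 calls (1333 and 1386).

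Whether the papain response differs between the sorted libraries of the cell types was tested directly. Fibroblast markers had median changes of 4.51 in basophils, 5.10 in CD11c-negative eosinophils and 0.57 in natural helper cells, before subtraction of the median of all genes. In naive natural helper cells these markers already had medians of 18 and 26 FPKM, against 1 and 1 in naive basophils. Naive eosinophils had 0 and 1. After papain the medians were 28 and 36 in natural helper cells, 147 and 20 in basophils and 59 and 29 in CD11c-negative eosinophils. The smaller change in natural helper cells thus started from a higher naive level. For genes such as Sparc, a response of the sorted cells therefore cannot be told apart from RNA of other lung cells. Between natural helper cells and basophils 963 genes differed, 302 with the higher response in natural helper cells and 661 with the higher response in basophils. The first share was 31.4%, against 37.5% after median-ratio scaling and 57.1% after quantile normalization, so the balance depends on scaling. Il18rap differed by 4.75 ± 0.44 (adjusted p = 0.00181), with a response of 1.46 in natural helper cells and -3.29 in basophils, and the matrix gene Sparc by -6.14 ± 0.73 (adjusted p = 0.00387), with 0.24 and 6.38. Between CD11c-negative eosinophils and basophils 336 genes differed (107 and 229), and between CD11c-negative eosinophils and natural helper cells 172 (85 and 87), among them Ccl7 (5.09 ± 0.61, adjusted p = 0.0133, up to 0.0746 without papain natural helper cell library 1). For CD11c-negative eosinophils and basophils the split of 107 and 229 turned round to 126 and 81 after median-ratio scaling and 137 and 62 after quantile normalization. For these eosinophils and natural helper cells, 49.4% were higher in eosinophils, against 61.7% and 57.9%. The median difference of all genes was -0.36, -0.27 and 0.05 in these comparisons. Leaving out single libraries gave 288 (without papain natural helper cell library 1) to 1691 (without papain basophil library 1) genes for the comparison of 963. It gave 20 (without naive basophil library 2) to 930 (without papain basophil library 1) for that of 336 and 12 (without papain natural helper cell library 1) to 152 (without naive natural helper cell library 2) for that of 172. With a group mean of 5 FPKM or more the counts were 631, 180 and 109, and with the compared groups alone 529, 338 and 796.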

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

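All tests in this part were chosen after the results were seen, except the comparisons of responses between cell types, which were planned. A further test, of a single dilution factor for the 146 naive basophil genes, was dropped after its result was seen, because these genes were picked on the naive libraries and incoming cells can add to them too.

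A difference between groups drew attention to the papain response, which differed between natural helper cells and basophils for 963 genes, between CD11c-negative eosinophils and basophils for 336, and between CD11c-negative eosinophils and natural helper cells for 172. These are differences between sorted libraries, in which RNA of other lung cells cannot be told apart from a response of the sorted cells. Naive natural helper cells had fibroblast markers at medians of 18 and 26 FPKM. Naive basophils had 1 and 1, and naive eosinophils 0 and 1. Higher in natural helper cells than in basophils were the responses of Il18rap (4.75), Il1r2 (4.39), Ctsg (4.38), Irf4 (4.15) and Hhex (3.88), and lower were those of the lymphoid chemokine genes Ccl21a (-7.17), Ccl21b (-6.60) and Ccl21c (-6.49) and the matrix genes Mgp (-6.59) and Sparc (-6.14). The responses in natural helper cells and basophils were 1.46 and -3.29 for Il18rap, 3.89 and -0.50 for Il1r2 and 0 and -4.38 for Ctsg. They were 3.33 and -0.81 for Irf4 and 1.65 and -2.23 for Hhex. For the lower genes they were -2.90 and 4.27 for Ccl21a, -2.78 and 3.82 for Ccl21b and -2.76 and 3.73 for Ccl21c. Mgp had 0.88 and 7.47 and Sparc 0.24 and 6.38. Il18rap, Sparc and Ccl21b passed without any 1 of the 8 libraries, whereas adjusted p rose to 0.145 for Mgp, 0.131 for Irf4 and 0.159 for Ctsg without papain natural helper cell library 1. The adjusted p rose to 0.0518 for Il1r2, 0.0638 for Hhex, 0.0553 for Ccl21a and 0.0514 for Ccl21c without naive basophil library 2.

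Between CD11c-negative eosinophils and basophils, the responses of Ufsp1 (4.45), Spib (3.95) and Cyp11a1 (3.80) were higher in eosinophils, and those of Gdf15 (-5.57), Jup (-4.54), Siglece (-4.34), Trem3 (-4.28) and Slc40a1 (-4.20) were lower. Between CD11c-negative eosinophils and natural helper cells, the responses of Clec3b (5.65), Dcn (5.58), Sparc (5.22), Ccl7 (5.09) and Ly6d (5.02) were higher in eosinophils, and those of Il1r2 (-4.40), Ttc39c (-4.18), Adap1 (-3.80), Slc2a6 (-3.54) and Zeb2 (-3.39) were lower. The responses in eosinophils and natural helper cells were 5.04 and -0.62 for Clec3b, 5.88 and 0.30 for Dcn and 5.45 and 0.24 for Sparc. They were 5.71 and 0.62 for Ccl7 and 1.31 and -3.70 for Ly6d. For the lower genes they were -0.51 and 3.89 for Il1r2, -1.17 and 3.01 for Ttc39c and -0.90 and 2.90 for Adap1. Slc2a6 had -2.22 and 1.32 and Zeb2 -1.55 and 1.84. None of these genes kept its call in every fit that left out 1 library; those counts went down to 20 (without naive basophil library 2) and 12 (without papain natural helper cell library 1).

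The fall of basophil genes in papain basophil libraries was weighed against 3 technical explanations. The first was a lower share of basophils with all other cell types rising alike. It was tested on the 8 lists whose naive level was not highest in basophils. Fibroblast markers, which started from 1 and 1 FPKM, and eosinophil markers lay 4.51 apart in their medians. Their quartiles were 2.62 and 5.30 against -0.74 and 1.53. These values argue only against an even rise. A lower share of basophils with certain cell types in their place would also give unequal rises, so lower purity remains open. Library scaling was argued against by a median of -3.11 for basophil markers after quantile normalization. RNA of structural and myeloid lung cells may account for part of it: 78.7% of their 47 markers (37) were higher in both papain libraries than in both naive ones, against 37.5% of all genes tested (16.7% by chance with no shift) and a bound of 80% set for this explanation, although the sort on FceR1 and CD49b should remove intact cells of these types. It cannot be told apart from a response of the basophils themselves, including lower Il4 and Il13, which remains open and untested.

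The rise of structural genes in papain eosinophil libraries was weighed in the same way. RNA of structural lung cells is a candidate source: 84.2% of the 19 fibroblast and epithelial markers (16, not Acta2, Epcam or Ager) were higher in all 4 papain libraries than in both naive ones, against 19.4% of all genes tested (6.67% by chance with no shift), with Sftpc at 410 to 1183 FPKM and Col1a1 at 40 to 97, although the sort on SiglecF should remove such cells. Library scaling was argued against by medians of fibroblast markers of 4.69 and 5.39 after quantile normalization in the 2 gates. Of these markers, 2 of 7 fibroblast and 10 of 12 epithelial ones had 1 FPKM or more in naive eosinophils. The 84.2% counts the same markers whose rise is to be explained, so it cannot tell such RNA apart from a response of the eosinophils. A response of the eosinophils to papain remains open and untested. Whether RNA of macrophages adds to other rises in these libraries, such as Ccl2 and Ccl7, was not tested.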

How the results depend on the processing

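The limits of the document come first. Most groups have 2 libraries and the 3'UTRKO genotype has 1, the labels do not say whether replicates are separate animals, and the file is rounded to whole FPKM. Counts of calls therefore depend on the settings below. Unless fewer genes, libraries or degrees of freedom explain a difference, the cause was not tested. No call of a named gene changed its direction in any setting. Of the named calls, 29 of 55 in basophils, 1 of 16 in natural helper cells, 6 of 24 in CD11c-negative eosinophils, 20 of 44 in CD11c-positive eosinophils and 8 of 16 in the 3'UTRKO comparison were kept in every fit that left out 1 library. A further 2 in natural helper cells were kept in the fits that tested them, but were not tested in all 4. For differing responses this held for 3 of 10, 0 of 10 and 0 of 10 genes. The planned count-based alternative was not run because the values are not counts.

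With a pseudocount of 0.1, calls were 524 in CD11c-negative eosinophils, 43 between the CD11c gates and 137 for the 3'UTRKO library. Differing responses of CD11c-negative eosinophils and natural helper cells were 374, naive basophil genes 229, naive natural helper cell genes 733, and lists in CD11c-positive eosinophils 4. With a pseudocount of 5 they were 184 in CD11c-negative eosinophils and 3 between the gates. The same responses then differed in 114 genes, and naive sets held 89 genes in basophils, 192 in eosinophils and 142 in natural helper cells. Without a filter there were 13 calls between the gates and 215 for the 3'UTRKO library. With a filter of 5 FPKM, which leaves fewer genes, there were 35 in natural helper cells, 1 between the gates and 36 for the 3'UTRKO library. Responses then differed in 619 genes between natural helper cells and basophils, 126 between CD11c-negative eosinophils and basophils, and 95 between these eosinophils and natural helper cells.

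Median-ratio scaling gave 52 calls in natural helper cells, 1 between the gates and 52 for the 3'UTRKO library. It gave 207 and 81 genes for responses of CD11c-negative eosinophils against basophils and natural helper cells, and 4 lists in basophils. Quantile normalization gave 56, 1 and 50 calls, 199 and 76 genes for those responses, 5 lists in basophils and 7 in CD11c-negative eosinophils. Robust eBayes gave 51, 1 and 45 calls and 110 and 106 genes. With a minimum log2 change of 1, 4 calls remained between the gates. With an estimated correlation 0 pathway lists were called in each of the 6 comparisons.

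The replicate block left fewer degrees of freedom, and the labels do not pair replicates; residuals of equal replicate numbers correlated at 0.116 in basophils, -0.077 in natural helper cells and at most 0.062 in eosinophils. With the replicate block calls were 107 in CD11c-negative eosinophils, 1 between the gates and 24 for the 3'UTRKO library. Responses differed in 469 genes between natural helper cells and basophils, and in 131 and 13 between CD11c-negative eosinophils and basophils or natural helper cells. Under the replicate block naive sets held 89 genes in basophils and 209 in natural helper cells.

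With the compared groups alone calls were 467 in basophils, 521 in natural helper cells, 1024 in CD11c-negative and 735 in CD11c-positive eosinophils, 157 between the gates and 2719 for the 3'UTRKO library. Responses differed in 529 genes between natural helper cells and basophils and in 796 between CD11c-negative eosinophils and natural helper cells. Fewer libraries do not by themselves explain the counts that rose. The median standard deviation in these fits was 0.425 in basophils and 0.0837 to 0.318 in the other 5 pairs of groups, against 0.392 with all groups, and whether it accounts for the counts was not tested. Among the settings added after seeing the data, genes without a near-identical copy gave 40 calls for the 3'UTRKO library, and genes other than small RNAs gave 5 between the gates. Calls with a group mean of 5 FPKM or more were 59 in natural helper cells, 1 between the gates and 52 for the 3'UTRKO library. For responses they were 631 between natural helper cells and basophils, 180 between CD11c-negative eosinophils and basophils, and 109 between these eosinophils and natural helper cells.

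Leaving out 1 library gave 1228 to 3513 calls in basophils, 52 to 126 in natural helper cells, 44 to 161 in CD11c-negative and 371 to 2070 in CD11c-positive eosinophils, 2 to 498 between the gates and 25 to 30 for the 3'UTRKO library. Differing responses were 288 to 1691, 20 to 930 and 12 to 152 genes. Naive sets held 112 to 137 genes in basophils, 225 to 325 in eosinophils and 249 to 447 in natural helper cells. Pathway lists called were 5 to 9 in basophils, 4 to 8 in natural helper cells, 1 to 5 in CD11c-negative and 1 to 6 in CD11c-positive eosinophils, 1 to 7 between the gates and 5 to 7 for the 3'UTRKO library.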

Other observations

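The tests of the 3'UTRKO position and the choice of the genes in the paragraphs below came after the values were seen; the test of near-identical copies over all calls was set before its result was seen, and that within the ribosomal protein genes after it. Genes that set naive cell types apart moved under papain to different extents. The 146 genes of naive basophils had median log2 ratios of -1.86 and -1.27 in the papain basophil libraries, with 139 and 130 of them below the naive mean. The 306 genes of naive eosinophils had medians from -0.44 to -0.76 in the 4 papain libraries, and the 414 genes of naive natural helper cells -0.10 and -0.03, with -0.13 in the 3'UTRKO library. These genes were picked on the naive libraries, so some fall is built in, and the difference between the cell types was not tested for these sets. The basophil set also holds 1 B cell marker, and whether fewer B cells in the papain sorts add to its fall was not tested.

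The papain basophil libraries differed from each other in lymphoid and macrophage genes. Library 1 had 114 FPKM of Icos, 105 of Cxcr6, 408 of Marco and 4074 of Lyz2, and library 2 had 0, 2, 10 and 368. Library 2 had more of the antimicrobial lectin Reg3g (2362 against 210) and of Scgb3a1, a secretory airway gene (8649 against 578). In naive natural helper cells the lymphatic chemokine Ccl21a had 103 and 102 FPKM, against 11 and 15 after papain and 1 in the 3'UTRKO library. S100a8 and S100a9, abundant in neutrophils, had 1039 to 1677 and 895 to 1249 FPKM in CD11c-negative and 3975 to 5489 and 3140 to 3885 in CD11c-positive eosinophils, without passing the test (adjusted p = 0.626 and 0.635). Haemoglobin transcripts were found in libraries of all 3 cell types. Hba-a1 had 512 and 137 FPKM in naive, 1086 and 539 in CD11c-negative and 326 and 267 in CD11c-positive eosinophils. It had 94 and 143 in naive and 563 and 75 in papain basophils, and 163 and 6 in naive and 30 and 46 in papain natural helper cells.

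The change of ribosomal protein genes in the 3'UTRKO library may come from reads shared with near-identical gene copies. Of the 79 called genes with a sequence, 35.4% had such a copy, against 9.6% of uncalled genes of like expression (8% of all uncalled genes; Fisher's exact p = 7.48e-12), and without ribosomal protein genes the shares were 27.9% and 7.7% (Fisher's exact p = 6.1e-07). In the other papain comparisons called genes had copies no more often than uncalled ones, for example 6.3% and 8.8% in basophils. Within the ribosomal protein genes, however, 9 of 11 called (81.8%) and 49 of 72 uncalled genes (68.1%) had a copy (Fisher's exact p = 0.491), and Rpl34 and Rpl30, which fell to 28 and 42 FPKM, shared 9.2% and 12.2% of their words, below the 20% set for a copy. For this family shared reads therefore cannot be told apart from other sources, as most of its members have copies and the assignment of reads cannot be seen in FPKM; a strain or sex difference (Xist at 0 and Y-linked genes present only in this library) also remains open, and no biological explanation was tested.

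A hypothesis for the 3'UTRKO library is that it lies part of the way from naive to papain natural helper cells. Its position on that axis (0 naive, 1 papain) was 0.26 and -0.07 in 2 estimates that swap the naive and papain libraries setting the axis and the scale. It was 0.29 and 0.17 with the other pairing of libraries. Without copies and ribosomal protein genes the 4 estimates lay between 0.06 and 0.33. The estimates of 0.26 and -0.07 lie on both sides of 0, all use the same 3'UTRKO library, and its sex differs as well, so an intermediate state cannot be told apart from a naive-like one with a single library.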
